A study of Homo sapiens with 16 samples.

How the data were processed

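Total RNA of L1236 cells was extracted with TRIZOL, converted to sense-strand cDNA, fragmented, labelled with biotin and hybridised to Affymetrix whole-transcript arrays, per the labels' protocols. The cells grew in RPMI with fetal bovine serum. The deposited values are log2 signals: RMA and Partek are named, without versions, in the submitters' processing notes, and base 2 was taken from RMA's usual output and the value range (2.07 to 14.1 at gene level, 1.88 to 15.1 at exon level), since no source used here states it. RMA subtracts a background estimate, equalises the distributions of the arrays and summarises probes, so a global shift between groups would be removed and dim signals compressed. Genome build, annotation version and any filters are not given in the sources used here. The titles exist once with a gene-level and once with an exon-level summary, and 4428 of 4428 shared features had identical values at tolerance 0, so the exon-level samples were used as a second summary of the same 8 arrays and never as further replicates. No array scan date or slide was among the files used here, so array batches could not be tested.

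The platform annotation table paired probe sets with genes. Of 33297 gene-level probe sets, 19460 had 1 symbol, 1754 several and 12083 none; of 257430 exon-level probe sets, 224320 had 1, 10159 several and 22951 none. Probe sets with several symbols were never named. Old symbols were updated through gene identifiers of the RefSeq annotation of GRCh38.p14, which was used only for names and for the order of neighbouring genes, so no coordinates are printed. For each gene the probe set with the highest mean was kept, giving 18395 genes; 788 had several probe sets, and in 0 of them did probe sets move by over 1 log2 unit in opposite directions. Genes with a mean under the 25th percentile were left out, which left 13796 tested genes with means of 4.78 or more. The exon-level table had the same filter, which left 168240 probe sets.

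Groups came from the treatment label (uninduced or induced). Limma 3.58.1 in R 4.3.3 fitted B code, last number and induction label to the 8 arrays (residual degrees of freedom 4, prior 6.27), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05; every adjusted p for a gene comes from limma. Interactions of the induction label with B code and with last number were tested in separate fits. RELB was also tested with an exact permutation test over the 8 values. The 25 gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Exon usage was tested with diffSplice (F test) in genes with 3 or more exon-level probe sets. Input was read with the R package data.table (version 1.17.8), and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

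The design, the gene lists and the rule for named genes were fixed before the data were examined. The rule named RELB; the 10 largest rises and 10 largest falls among genes passing the threshold and moving the same way in all 4 pairs; the 4 lowest p of each list plus RELA, REL, NFKB1 and NFKB2; the 4 largest in each direction for the other effects, filled by unadjusted p; and the 5 lowest p for exon usage. Y-linked genes, XIST and TSIX are not reported here and were skipped in naming, which left out 1 gene that the rule would have named.

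The scripts were tested on simulated values built from the real means and spreads. For the induction label, 86% of 50 genes changed by 0.5 log2 and 100% of those changed by 1 or more were recovered among 13796, and 8.53% of calls were false. For the interaction with B code, 2% of changes of 0.5 and 76% of changes of 1 were recovered, and for that with last number 6% and 86%. Exon usage recovered 30% of genes with 1 probe set shifted by 1 log2 and 96% at a shift of 2, with the false calls given in the report. Alternatives were the filter, quantile normalisation, median centring, the mean of a gene's probe sets, a variance trend with robust fitting, exon-level means, a looser threshold of 0.1, the pair as a fixed or random block, no covariates, other list tests, the Simes test and each array left out in turn.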

Results

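The series measured RNA from L1236, an established human Hodgkin lymphoma cell line, on Affymetrix whole-transcript arrays. Cells carried a retrovirus encoding a short hairpin RNA against RELB, the DNA-binding subunit of the alternative NF-kB pathway. By the treatment protocol, infected cells were split: part was left uninduced and part was treated with doxycycline to switch the hairpin on. The question was how gene expression changed when RELB was depleted. The 16 samples are 8 arrays, each summarised once per gene and once per exon-level probe set: all 4428 features listed in both tables held identical values in the 8 same-titled columns. Each group therefore has n = 4 arrays, in 4 uninduced and induced pairs that cross a B code (B_1 or B_4) with a last number (1 or 4), whose meanings the labels do not state. Nothing in the labels says that the 4 arrays of a group came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. Among uninduced arrays, correlations within a B code (0.9948 or higher) exceeded those between B codes (0.9925 or lower). Those 4 arrays may thus hold fewer than 4 independent units. Among induced arrays the lowest within a B code was 0.9919 and the highest between B codes 0.9934. Values are log2 signals after RMA, and the number of arrays limits the precision. Column medians ran from 5.79 to 5.88 in the gene-level table and from 6.51 to 6.59 in the exon-level table.

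RELB mRNA, the target of the hairpin, did not fall detectably in the arrays labelled induced. Its log2 signal was 7.40 ± 0.13 in arrays labelled uninduced and 7.25 ± 0.11 in arrays labelled induced (SD, n = 4 each). The difference of -0.15 ± 0.09 (SE) corresponds to a level 9.69% lower, with a 95% interval from 21.7% lower to 4.19% higher. The exact permutation test, two-sided, gave p = 0.171, where 0.0286 is the smallest p that 4 against 4 arrays allow, and limma gave an adjusted p of 0.212. At gene level RELB was lower in the induced array of 4 of 4 pairs, in replicate 1 only from 7.225 to 7.219. As the mean of its exon-level probe sets it was higher in the induced array of replicates 1 (7.52 to 7.64) and 2 (7.522 to 7.527). By that mean it was lower in replicates 3 (7.81 to 7.53) and 4 (7.66 to 7.36). Of the 11 exon-level probe sets of RELB, 7 were lower and 0 passed the limma threshold, with log2 differences from -0.58 to 0.31. Because the targeted gene does not bear out the labels, the groups are called arrays labelled induced and arrays labelled uninduced below, and every direction drawn between them rests on the labels alone.

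**Figure D1:**
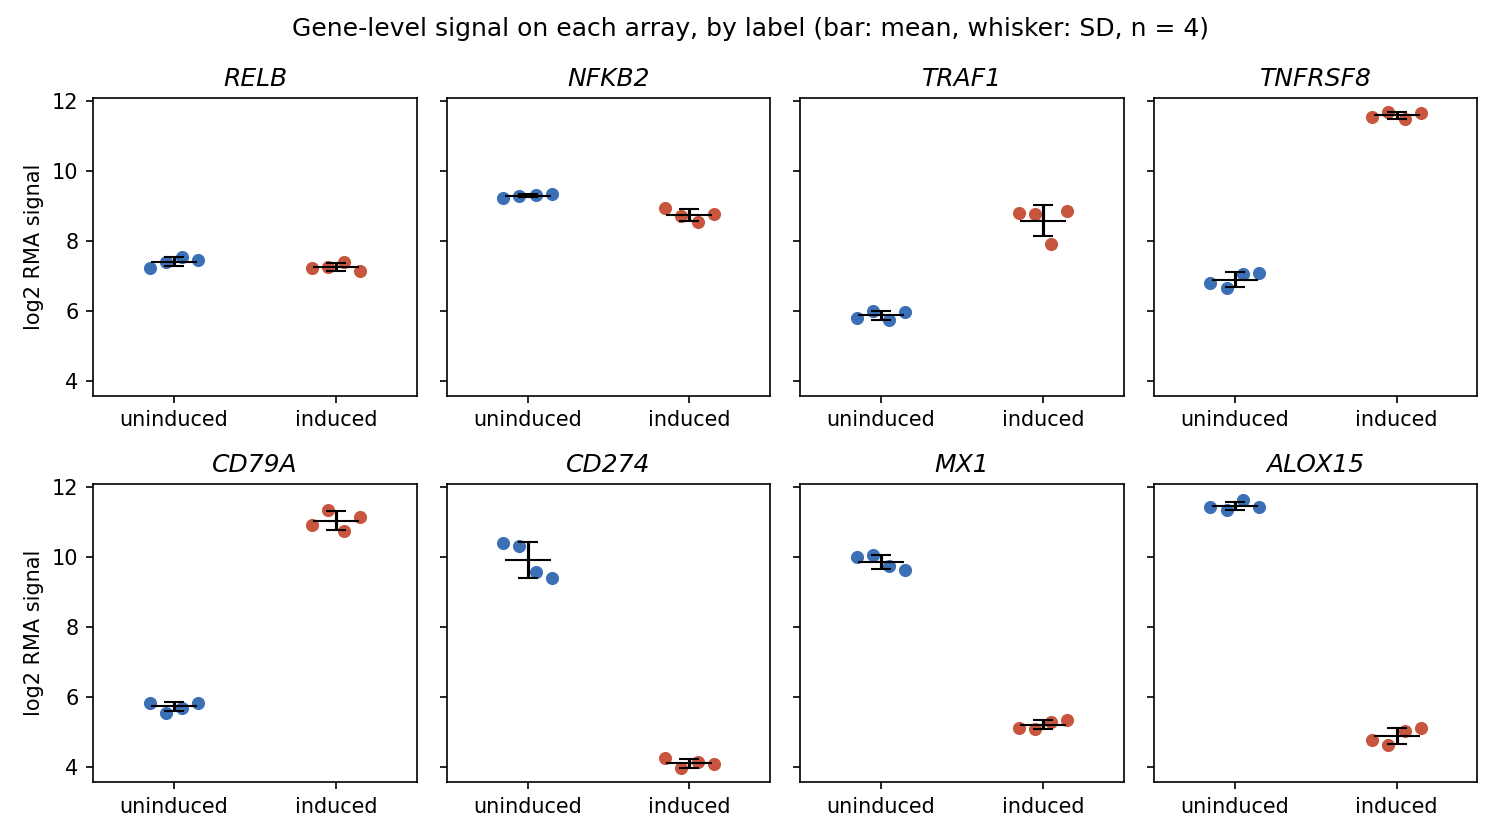
Log2 RMA signal of 8 genes on each array, with arrays labelled uninduced and induced side by side (points, replicates 1 to 4 from left to right; bar, mean; whisker, SD; n = 4). RELB means were 7.40 and 7.25, while TNFRSF8 means were 6.89 and 11.59 and CD274 means were 9.91 and 4.11.

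The arrays labelled induced carried a different expression profile from the arrays labelled uninduced. SLC38A1, a glutamine transporter, was 123-fold higher in the arrays labelled induced (log2 difference 6.94 ± 0.15, SE, n = 4 per group), and CD38, a surface ectoenzyme of activated B cells and plasma cells, was 98.3-fold higher (6.62 ± 0.10). GSTM1, a glutathione transferase, was 144-fold lower (-7.17 ± 0.11), and SULF1, an extracellular sulfatase, was 135-fold lower (-7.07 ± 0.12). In all, 7656 of 13796 tested genes (55.5%) passed limma at an adjusted p under 0.05, 3744 of them higher and 3912 lower, and 7407 of the called genes moved the same way in 4 of 4 pairs. The 4 values of one group did not overlap the 4 of the other for 6868 genes (49.8%), against 2.86% by chance.

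Differences of at least 2-fold were seen for 952 higher and 1327 lower genes, and of at least 16-fold for 61 higher and 126 lower genes. The other largest rises were the lymphocyte receptor SLAMF6 (6.45 ± 0.12), the sialyltransferase ST6GAL1 (6.34 ± 0.11), glutamine synthetase GLUL (6.20 ± 0.10), the retinal dehydrogenase ALDH1A1 (6.03 ± 0.15), the ectonucleotidase ENTPD1 (5.91 ± 0.16), HLA-DRB5 (5.71 ± 0.13), the orphan receptor GPR160 (5.69 ± 0.08) and GPRIN3 (5.47 ± 0.11). The other largest falls were monoamine oxidase MAOA (-6.94 ± 0.12), the interleukin-13 receptor chain IL13RA1 (-6.84 ± 0.10), the G protein subunit GNAQ (-6.77 ± 0.11), the cytochrome CYP1B1 (-6.66 ± 0.09), the peptidase DPP4 (-6.59 ± 0.09), the lipoxygenase ALOX15 (-6.56 ± 0.09), the interferon-induced gene IFI44L (-6.50 ± 0.11) and the sorting receptor SORL1 (-6.30 ± 0.11). All of these differences are log2 values with the SE of the fit, and each had an adjusted p of 2.88e-10 or lower; 1 gene of this size is not reported here. GSTM1 and HLA-DRB5 have near-identical relatives whose RNA the probes may share, so their gene assignment is uncertain. Signals near the bottom of the range include array background, so folds of genes dim in one group understate the difference.

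**Figure D2:**
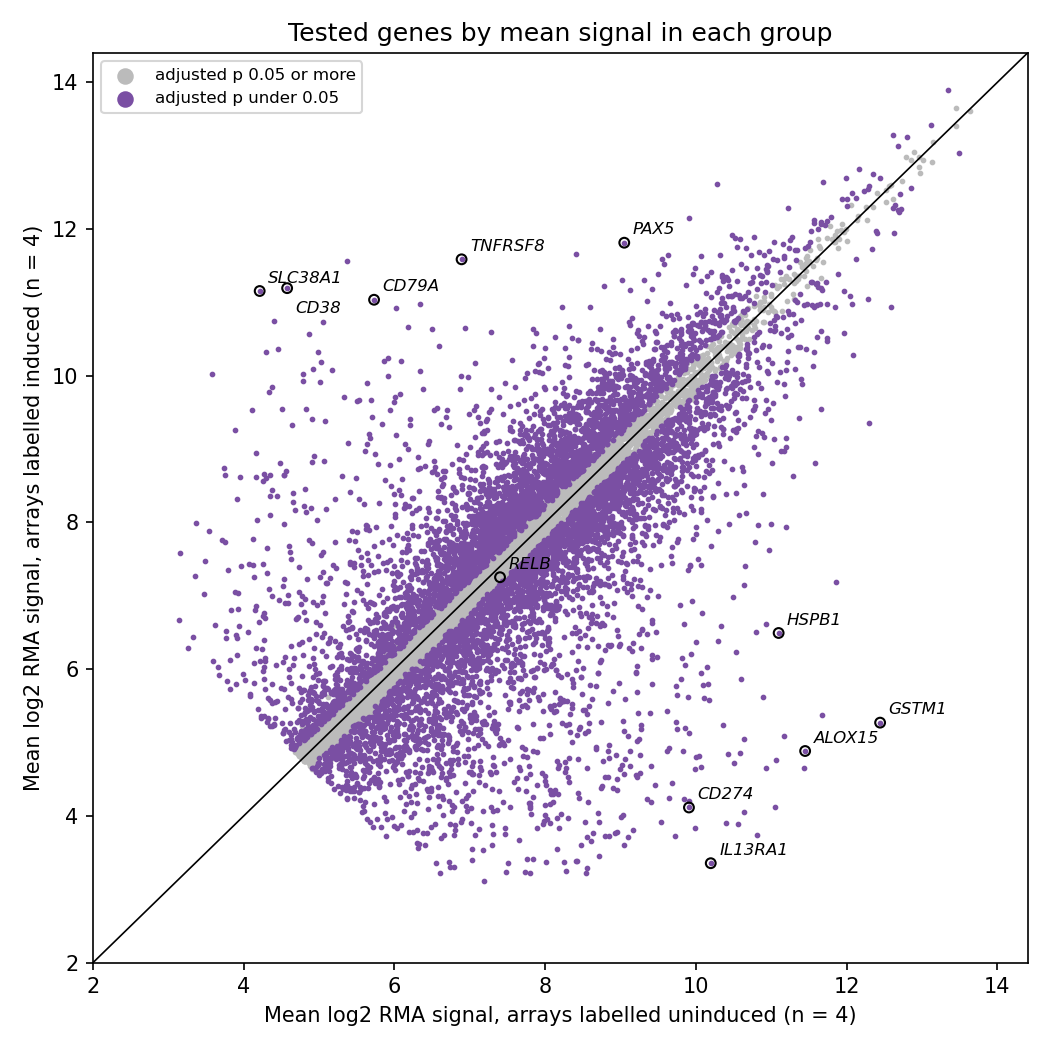
Mean log2 RMA signal of each tested gene in arrays labelled uninduced (horizontal axis) and induced (vertical axis), n = 4 each; purple points passed limma at an adjusted p under 0.05 and the line marks equal means. RELB lies near the line, and the genes circled far from it include GSTM1 (12.44 against 5.27) and SLC38A1 (4.21 against 11.16).

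Components of the NF-kB pathway itself moved in both directions. Of 23 measured NF-kB subunits and regulators, 10 rose, 7 fell and 6 did not pass; adjusted over the list alone, 18 passed. NFKBIZ, a nuclear IkB protein, was 13.3-fold higher in the arrays labelled induced (3.73 ± 0.09), TRAF1 was 6.51-fold higher (2.70 ± 0.15) and TRAF3 3.55-fold higher (1.83 ± 0.11), while the deubiquitinase CYLD was 4.36-fold lower (-2.13 ± 0.11). Among the subunits, NFKB2 fell (-0.56 ± 0.10, adjusted p = 0.000602) and RELA rose (0.24 ± 0.08, adjusted p = 0.0233), a call lost without the uninduced array of replicate 2, 3 or 4 or the induced array of replicate 1 or 4 (adjusted p from 0.0547 to 0.0737). REL (0.20 ± 0.09, adjusted p = 0.0792) and NFKB1 (0.16 ± 0.09, adjusted p = 0.165) did not pass.

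Target genes of NF-kB in activated B cells were mostly lower in the arrays labelled induced: 19 of 30 fell, 7 rose and 4 did not pass, and 26 passed when adjusted over the list alone. SLAMF1 was 43.1-fold lower (-5.43 ± 0.17), the costimulatory ligand CD80 20.7-fold lower (-4.37 ± 0.12), TNF 9.94-fold lower (-3.31 ± 0.09) and the chemokine CCL5 9.52-fold lower (-3.25 ± 0.09). The list was called by camera (adjusted p = 0.00148, down), and the call was lost with an estimated correlation (adjusted p = 0.956). Of 12 measured targets of the alternative pathway, 3 rose, 6 fell and 3 did not pass, and 9 passed when adjusted over the list alone. VCAM1 (-3.41 ± 0.13) and the survival gene BCL2L1 (-3.26 ± 0.16) fell, while the complement receptor CR2 (4.44 ± 0.19) and IL10 (3.44 ± 0.14) rose, and camera did not call this list (adjusted p = 0.614).

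Markers of Hodgkin and Reed-Sternberg cells, the malignant cells of the disease, split. Of 26 measured, 15 fell, 7 rose and 4 did not pass, with 22 passing when adjusted over the list alone. The checkpoint ligands CD274 (PD-L1) and PDCD1LG2 (PD-L2) were 55.5-fold and 33.0-fold lower in the arrays labelled induced (-5.79 ± 0.16 and -5.04 ± 0.11), and the kinase JAK2 was 9.63-fold lower (-3.27 ± 0.08). CD274, PDCD1LG2 and JAK2 lie in the same stretch of neighbouring genes, most of which were lower (see Other observations). Their falls may thus not be independent of each other. JAK2 is also a member of the JAK-STAT list below. TNFRSF8, which encodes the diagnostic marker CD30, was 25.9-fold higher (4.70 ± 0.11). Camera called the list down (adjusted p = 0.0497), and the call was lost with an estimated correlation (adjusted p = 0.956). B-cell genes had more rises than falls: 10 of 21 rose, 5 fell and 6 did not pass, with 15 passing when adjusted over the list alone. CD79A, a B-cell receptor chain, was 39.6-fold higher (5.31 ± 0.12), CD22 17.2-fold (4.11 ± 0.13), RASGRP3 14.5-fold (3.86 ± 0.09) and the B-lineage factor PAX5 6.80-fold (2.76 ± 0.08). Camera did not call the B-cell list in the main fit (adjusted p = 0.0679). It did with the median filter (0.0371) and with quantile normalisation (0.0445), and not with an estimated correlation (0.956).

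**Figure D3:**
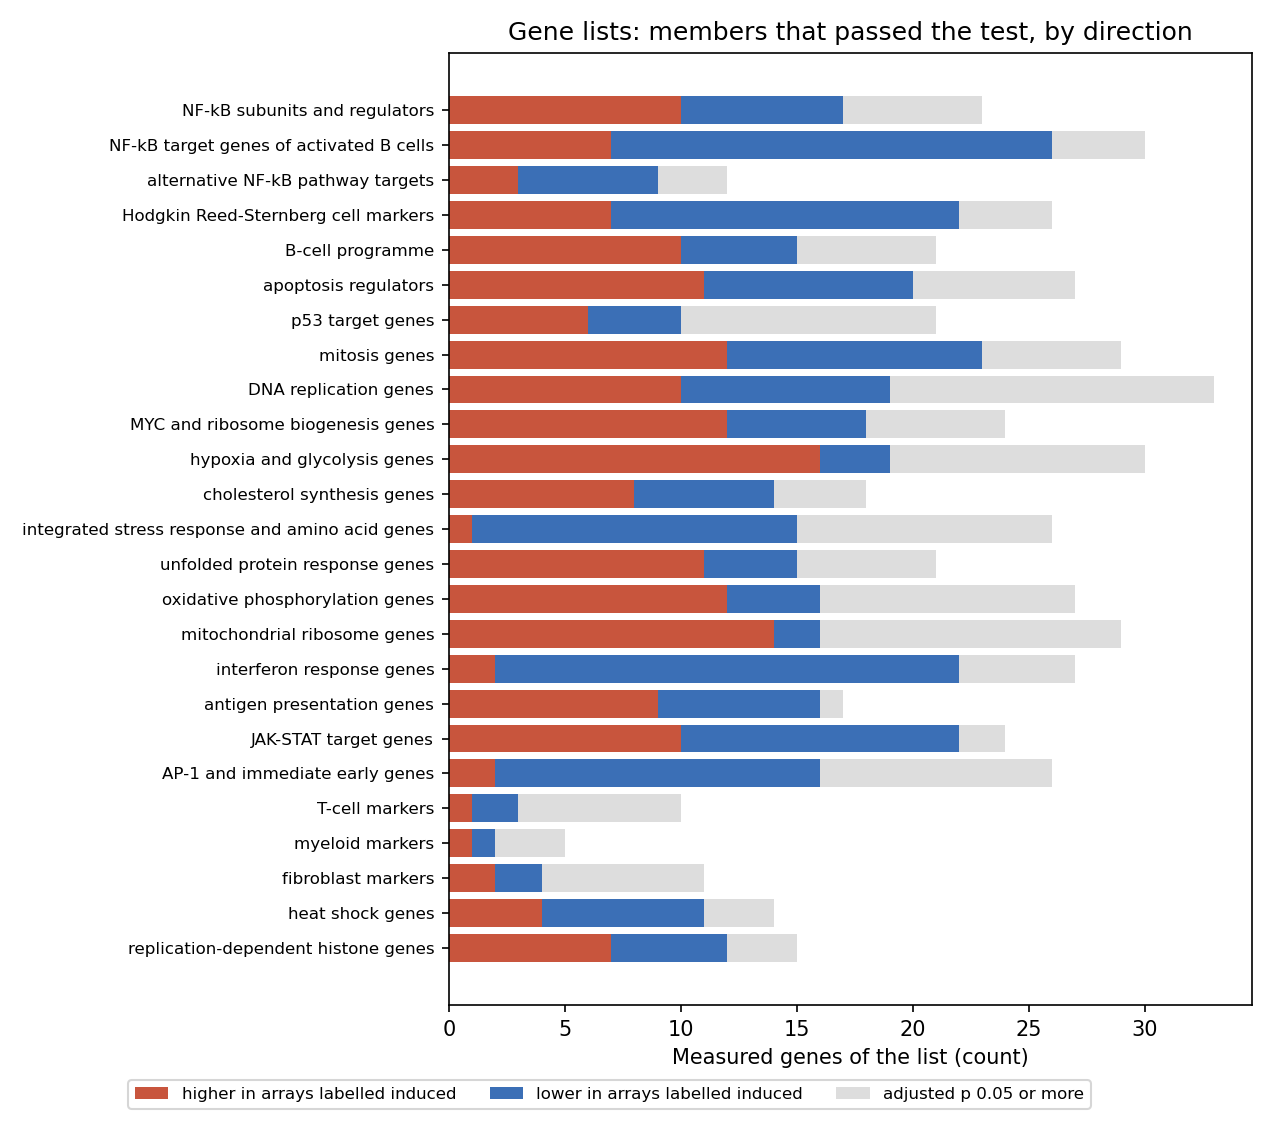
Number of measured genes of each of the 25 lists (horizontal axis, count) that passed limma and were higher (red) or lower (blue) in arrays labelled induced than in arrays labelled uninduced, or did not pass (grey); n = 4 arrays per group. Interferon response genes had 20 lower and 2 higher, and B-cell genes had 10 higher and 5 lower.

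Most interferon response genes were lower in the arrays labelled induced. Of 27 measured, 20 fell, 2 rose and 5 did not pass, and 22 passed when adjusted over the list alone. The antiviral GTPase MX1 was 25.1-fold lower (-4.65 ± 0.12), IFI44 17.7-fold lower (-4.15 ± 0.10) and the RNA sensor RIGI 8.34-fold lower (-3.06 ± 0.09). Camera called the list down (adjusted p = 0.000109), and the call was lost with an estimated correlation (adjusted p = 0.546). AP-1 and immediate early genes fell in 14 of 26 cases, rose in 2 and did not pass in 10, with 16 passing when adjusted over the list alone. BATF3 was 19.9-fold lower (-4.31 ± 0.13), the phosphatase DUSP6 10.2-fold lower (-3.35 ± 0.13), ATF3 9.52-fold lower (-3.25 ± 0.12) and JUN 7.52-fold lower (-2.91 ± 0.09). Camera called this list too (adjusted p = 0.00568, down), and the call was lost with an estimated correlation (adjusted p = 0.546).

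The list named JAK-STAT target genes, which also holds receptors and kinases of the pathway, split. Of its 24 genes, 10 were higher, 12 lower and 2 did not pass, with 22 passing when adjusted over the list alone. The cytokine receptor IL4R was 9.31-fold lower (-3.22 ± 0.09) and the feedback inhibitor SOCS1 5.95-fold lower (-2.57 ± 0.12), beside the falls of IL13RA1 and JAK2. Antigen presentation genes also split, with 9 of 17 higher, 7 lower and 1 not passing, and 16 passing when adjusted over the list alone. The class II chain HLA-DQA1 was 13.1-fold higher in the arrays labelled induced (3.71 ± 0.09) and cathepsin CTSS 10.8-fold higher (3.43 ± 0.12), while HLA-DOB was 6.32-fold lower (-2.66 ± 0.11) and the peptide transporter TAP1 4.32-fold lower (-2.11 ± 0.09). Camera called neither list (adjusted p = 0.526 for the JAK-STAT list and 0.580 for antigen presentation).

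Of 26 genes of the integrated stress response and amino acid supply, 14 fell, 1 rose and 11 did not pass (15 passed when adjusted over the list alone; camera adjusted p = 0.058). The serine synthesis enzyme PSAT1 was 26.6-fold lower in the arrays labelled induced (-4.73 ± 0.16), WARS1 4.55-fold lower (-2.19 ± 0.16) and SHMT2 1.94-fold lower (-0.96 ± 0.10). Of 21 genes of the unfolded protein response, 11 rose, 4 fell and 6 did not pass (15 when adjusted over the list alone; camera adjusted p = 0.0679), with XBP1 2.81-fold higher (1.49 ± 0.09), ERN1 2.23-fold (1.16 ± 0.10), HSP90B1 2.10-fold (1.07 ± 0.12) and SYVN1 higher (0.85 ± 0.10). Heat shock genes had 4 of 14 higher, 7 lower and 3 not passing (11 when adjusted over the list alone; camera adjusted p = 0.394). HSPB1 was 24.3-fold lower (-4.60 ± 0.10) and HSPA4L 15.9-fold lower (-3.99 ± 0.09), with smaller falls of DNAJA1 (-0.89 ± 0.10) and HSP90AB1 (-0.46 ± 0.08).

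Metabolic lists held more rises than falls, without a camera call in the main fit, though some gained one under the alternatives below. Hypoxia and glycolysis genes had 16 of 30 higher, 3 lower and 11 not passing (19 when adjusted over the list alone; adjusted p = 0.0679). PFKL, a phosphofructokinase, was 2.98-fold higher (1.57 ± 0.13), and the 3 falls were among the largest changes of the list: the collagen hydroxylase P4HA2 (-4.31 ± 0.10), the mitophagy gene BNIP3 (-3.66 ± 0.21) and ALDOC (-2.41 ± 0.22). Oxidative phosphorylation genes had 12 of 27 higher, 4 lower and 11 not passing (16 when adjusted over the list alone; adjusted p = 0.0679), with SDHA at 0.95 ± 0.10, NDUFS1 at 0.79 ± 0.08, NDUFA9 at 0.76 ± 0.10 and CYC1 at 0.72 ± 0.10. Mitochondrial ribosome genes had 14 of 29 higher, 2 lower and 13 not passing (16 when adjusted over the list alone; adjusted p = 0.0679), with TFAM at 1.04 ± 0.11, MRPL17 at 0.88 ± 0.10, TSFM at 0.66 ± 0.09 and MRPL12 at 0.65 ± 0.08. Cholesterol synthesis genes had 8 of 18 higher, 6 lower and 4 not passing (14 when adjusted over the list alone; adjusted p = 0.911). The sterol demethylase CYP51A1 was 53.1-fold lower (-5.73 ± 0.19), SC5D and NSDHL fell (-2.02 ± 0.12 and -1.03 ± 0.11), and the sterol carrier STARD4 rose (2.45 ± 0.17).

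Growth and death programmes showed no common direction in the arrays labelled induced. Mitosis genes had 12 of 29 higher, 11 lower and 6 not passing (23 when adjusted over the list alone), with DLGAP5 (1.75 ± 0.13), BUB1B (1.58 ± 0.11) and NUSAP1 (0.86 ± 0.09) up and CENPF down (-1.35 ± 0.08). DNA replication genes had 10 of 33 higher, 9 lower and 14 not passing (19 when adjusted over the list alone), with the primase PRIM1 4.62-fold lower (-2.21 ± 0.08), MCM6 lower (-0.76 ± 0.08), and CCNE2 (1.86 ± 0.16) and POLE (1.45 ± 0.08) higher. MYC and ribosome biogenesis genes had 12 of 24 higher, 6 lower and 6 not passing (19 when adjusted over the list alone), with ODC1 (-1.38 ± 0.10) and CAD (-0.91 ± 0.09) down and MYBBP1A (0.87 ± 0.10) and NOP16 (0.82 ± 0.08) up. Histone genes had 7 of 15 higher, 5 lower and 3 not passing (12 when adjusted over the list alone). H1-4 (2.34 ± 0.10) and H4C14 (2.05 ± 0.13) were higher, H2AC6 was lower (-0.89 ± 0.11), and H4C8 was lower (-1.73 ± 0.13) at gene level but 0.01 higher as the mean of its exon-level probe sets. Histone genes have near-identical copies, so their assignment is uncertain.

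Apoptosis regulators had 11 of 27 higher, 9 lower and 7 not passing (20 when adjusted over the list alone). The caspase inhibitor CFLAR was 5.83-fold lower (-2.54 ± 0.11) and the pro-death gene BCL2L11 3.59-fold lower (-1.84 ± 0.09), while CASP9 was 4.10-fold higher (2.04 ± 0.09) and BID 3.03-fold higher (1.60 ± 0.08). Among p53 targets 6 of 21 rose, 4 fell and 11 did not pass (9 when adjusted over the list alone), with the death receptor TNFRSF10B (1.05 ± 0.13) and MDM2 (0.79 ± 0.09) up and SESN2 (-1.38 ± 0.17) and GDF15 (-0.53 ± 0.08) down. Camera adjusted p was 0.811 for apoptosis, mitosis and DNA replication genes, 0.911 for p53 targets, 0.317 for MYC genes and 0.467 for both histone genes and NF-kB regulators.

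Markers of other cell types showed single large changes. Of 10 measured T-cell markers, 1 rose, 2 fell and 7 did not pass (3 when adjusted over the list alone): GATA3, also known in Hodgkin cells, was 36.6-fold lower in the arrays labelled induced (-5.19 ± 0.19), SH2D1A 9.65-fold lower (-3.27 ± 0.11) and ZAP70 4.26-fold higher (2.09 ± 0.09), with CD247 at 0.32 ± 0.15 (adjusted p = 0.0978). Of 11 fibroblast markers, 2 rose, 2 fell and 7 did not pass (4 when adjusted over the list alone): the protease FAP was 38.7-fold lower (-5.27 ± 0.17), FN1 2.29-fold lower (-1.20 ± 0.10), COL6A3 10.1-fold higher (3.34 ± 0.18) and PDGFRB 1.51-fold higher (0.59 ± 0.08). Of 5 myeloid markers, CD68 rose (0.76 ± 0.08) and ITGAM fell (-0.40 ± 0.13, adjusted p = 0.0215), a call lost without either array of replicate 1 or 4 (adjusted p from 0.0666 to 0.0867), and CSF1R (0.16 ± 0.10) and TYROBP (-0.06 ± 0.08) did not pass; the count was 2 when adjusted over the list alone. Mean signals were low for CD68 (5.28 labelled uninduced, 6.04 labelled induced), ITGAM (5.34, 4.94) and PDGFRB (4.85, 5.44). The gene-level column medians were 5.79 to 5.88. Camera adjusted p was 0.951, 0.927 and 0.811 for the T-cell, fibroblast and myeloid lists. The median, mean and camera direction of a list differed in sign for apoptosis, p53, DNA replication, cholesterol and T-cell genes. Camera called 4 of 25 lists with its preset correlation and 0 with an estimated one, and fry, which asks whether a list's genes move one way on balance, called 16. Without the uninduced array of replicate 3 camera called 8 lists, and without the induced array of replicate 3 it called 9.

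The labels' B codes and last numbers made smaller differences than the induction label. The median absolute log2 difference over all tested genes was 0.30 between arrays labelled induced and uninduced, 0.10 between B codes and 0.09 between last numbers. Limma called 0 genes between B codes (1911 at an unadjusted p under 0.05) and 0 between last numbers (971). Differences within each labelled group were taken as contrasts of the B code interaction fit to all arrays, with a shared estimate of the spread. These contrasts called 395 genes between B codes within the arrays labelled uninduced and 9 within the arrays labelled induced. Among genes by the naming rule, CXCL10, an interferon-induced chemokine, was higher under B_4 (1.04 ± 0.17, adjusted p = 0.192), as were PRICKLE1 (0.92 ± 0.18), H2BC12 (0.65 ± 0.10) and CMA1 (0.57 ± 0.11), and TNFRSF9 was lower (-0.88 ± 0.14), as were SOS2 (-0.68 ± 0.10), DENND5A (-0.63 ± 0.08) and FN1 (-0.62 ± 0.10), all missing the threshold. Without the induced array of replicate 4, the count between B codes was 65, and without that of replicate 3 it was 1. For the last number, EOLA1-DT (0.52 ± 0.11, adjusted p = 0.660) and ANKMY2 (-0.55 ± 0.12) lay at the ends of the named genes, with MIR134, LOC442132 and PALD1 between 0.47 and 0.50 and UBXN2B, RPGRIP1L and PDCL3 between -0.51 and -0.38.

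Differences between arrays labelled induced and uninduced had mostly the same direction under both B codes. Across genes, which are not independent replicates, the effects in B_1 and B_4 correlated at Pearson r = 0.963 and Spearman rho = 0.886, from sets that share no array, and 2460 of 2462 genes with an effect of at least 2-fold in B_1 had the same direction in B_4. The effect differed between B codes for 41 genes, 29 more positive and 12 more negative under B_4. SPX (2.23 ± 0.17), AKR1C2 (1.92 ± 0.31), BMP10 (1.89 ± 0.18) and DNM1P46 (1.61 ± 0.20) were the most positive, and SLFN11 (-2.12 ± 0.18), TRIM59 (-1.95 ± 0.15), SNORD14E and BTN3A3 (-1.47 ± 0.24) the most negative. SPX, for example, fell from 7.89 to 3.43 under B_1 and from 5.55 to 3.31 under B_4, so the codes differed in the arrays labelled uninduced. In the arrays labelled induced, SPX, BMP10 (3.69 and 4.01) and AKR1C2 (4.16 and 4.70) lay near the bottom of the range. A difference between B codes may not show there. Of the 41 genes, 33 had the larger B code difference in the arrays labelled uninduced. SLFN11 by contrast rose from 6.22 to 7.98 under B_1 and went from 6.50 to 6.14 under B_4. The count of 41 fell to 4, 3, 11 and 6 without the uninduced array of replicate 1, 2, 3 or 4, and to 25 and 18 without the induced array of replicate 2 or 4. It rose to 65 with median centring, 174 with a variance trend and robust fitting, and 128 at an adjusted p under 0.1.

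The effect of the induction label did not differ detectably with the last number: limma called 0 genes, with 407 at an unadjusted p under 0.05. MIR15A (1.39 ± 0.21), SELPLG (0.97 ± 0.18), GPR31 (0.99 ± 0.19) and RAB38 (0.86 ± 0.17) had the lowest unadjusted p among positive differences, and CHRNA7 (-1.31 ± 0.24), MTERF1 (-0.87 ± 0.18), MIR9-1HG and SLC25A24 (-0.90 ± 0.19) among negative ones, with an adjusted p of 0.999 each. Without the induced array of replicate 1 the count was 3.

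At exon level, 59621 of 168240 tested probe sets (35.4%) differed between arrays labelled induced and uninduced, 30130 higher and 29491 lower. The test for shifts of exons within a gene, apart from the gene as a whole, gave its lowest p for COL12A1, a fibril-associated collagen, where 16 of 58 probe sets lay above and 23 below the rest of the gene, with relative log2 differences from -3.47 to 4.74. TRIO, a guanine nucleotide exchange factor, had 16 of 61 above and 29 below, GABBR1 21 of 66 above and 20 below (-2.51 to 2.95), ABCA13 16 of 59 above and 21 below (-3.58 to 4.16), and ANK2 20 of 50 above and 26 below (-3.07 to 3.24). These 5 genes, named by p and not by size of shift, also fell at gene level, TRIO by 0.84 and ABCA13 by 5.70 on the log2 scale. Limma's diffSplice called 5938 of 14639 genes (40.6%). Of these, 5148 were tested at gene level and 4070 were called there, where 55.5% of all tested genes were called. In simulated data diffSplice gave 94 false calls among 14439 unchanged genes, 36.7% of its calls there, so single calls are uncertain. Only 200 genes were changed in that simulation, so the share of false calls does not carry over to the real data. Probe sets near background cannot follow a large fall of their gene, which the test also reads as a shift.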

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

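The test of RELB and the test of exon-level agreement were chosen after the results were seen; the tests of neighbouring genes, housekeeping genes and other splits of the arrays were set before, but the reading of the housekeeping test was changed after its result was seen, from speaking for a batch (a percentile of 5 or more) to deciding nothing.

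Of the tested genes, 55.5% differed between arrays labelled induced and uninduced while RELB did not fall clearly. The lower bound of the RELB 95% interval, -0.35 on the log2 scale, argues against a RELB mRNA fall of 2-fold or more between the groups. It bears on RELB depletion as the cause only if both groups held the same cells. The interval rests on a spread between arrays that may be technical, and RELB protein was not analysed here. A candidate explanation is that the groups held cells of different origin, for which the neighbouring-gene test is not specific. Such an origin would depart from the treatment protocol, by which infected cells were split into the groups. Medians over windows of 25 neighbouring genes spread 2.56 times as widely as with shuffled gene order, past the bar of 1.5 set beforehand. Last number, which varies within the groups, also passed it (1.56), and B code gave 1.28. For any of the 3, 0 of 1000 shuffles were as large. The passes differed in size: the spread beyond shuffled order was 0.220 for the induction label and 0.0390 for last number. That comparison of sizes was chosen after the results were seen. No label or file used here names an array or labelling batch, and the housekeeping test decides nothing about one: 43 housekeeping genes differed as much as genes of the same level (percentile 79.5 among 10000 matched lists; 20 rose and 9 fell), which a broad change of expression would also give. A response to doxycycline or to the hairpin, with or without effects of its own, was not tested, because the series as used here holds no doxycycline-only or non-targeting control.

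For the genes that differed by at least 16-fold, 96.3% of 2430 exon-level probe sets, counting those bright in the brighter group, moved with their gene by at least 1 log2 unit and 0 moved against it. These genes were chosen by a summary of the same probes on the same arrays, so the agreement decides nothing about a batch.

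The 8 arrays were also split in other ways, without covariates. Every other split mixes the labelled groups, whose large difference then widens the spread within each set. Low counts for the other splits were thus nearly fixed in advance. The main counts below show that the label split separates the arrays, and they do not exclude chance. The real split called 7288 genes and the highest of the other splits called 0 (1 of 35 splits as large). For exon-level probe sets the values were 60367 and 0 (1 of 35), and for exon usage 5708 and 52 (1 of 35). For gene lists, 18 of 35 splits called as many lists as the real split, which called 5 against a highest other count of 12, so chance was not excluded for the number of list calls. For B code and last number the real counts were 0 and the highest other split called 10 genes each (18 of 18 splits as large), a design in which no share under 0.05 can be reached with so few splits.

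The effect of the induction label differed between B codes for 41 genes by an interaction test. Of these, 33 differed between B codes within the arrays labelled uninduced and 6 within the arrays labelled induced. Between B codes, contrasts of the same fit to all arrays called 395 genes within the arrays labelled uninduced and 9 within the arrays labelled induced.

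Single arrays stood apart by Dixon's test in 9 of 242 tests made. Chance gives about 1 in 20, so this number is no higher than chance would give. In arrays labelled induced, replicate 3 was low for TRAF1 (7.90 against a median of 8.80 in the others, ratio 0.883), PFKL (9.38, ratio 0.844), STARD4 (10.75 against 11.39, 0.955) and TYROBP (5.83 against 6.02, 0.902). Replicate 1 was high for CD80 (6.30 against 5.62, 0.974) and replicate 4 high for IL10 (8.52 against 8.13, 0.952). In arrays labelled uninduced, replicate 1 was low for PFKL (8.05 against 8.33, 0.860), CYC1 (9.92 against 10.14, 0.874) and CTSS (5.39 against 5.73, 0.834).

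Among gene-level probe sets that the annotation table does not name, 2827 of 9062 tested (31.2%) differed between arrays labelled induced and uninduced, 2188 of them higher. What these probe sets measure was not tested, and array controls were not set apart.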

How the results depend on the processing

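The number of genes called for the induction label stayed between 6206 and 8388 under all alternatives run, RELB stayed between -0.22 and -0.07 with adjusted p from 0.0921 to 0.539, and exon-level and exon-usage counts stayed within 1.5 times their main values, including 6205 with the Simes test and 8454 with inverse-variance weights, an alternative chosen after seeing the data. In simulated data with 200 changed genes, 36.7% of calls were false with the main exon-usage test, 70.1% with Simes and 81.6% with the weights. False calls among 14439 unchanged genes numbered 94, 412 and 829. The shares depend on how few genes were changed and do not carry over to the real counts. The tests differ in error, so similar counts are no evidence of stability. Of the values of 120 named genes under alternatives, 2245 kept direction and side of the threshold, 9 lost the call, 6 gained it and 2 reversed. TYROBP and H4C8 reversed as means of exon-level probe sets (0.0092 and 0.0095); the cause was not tested. Same-numbered arrays did not all deviate together (correlations 0.16, -0.02, 0.11 and 0.02), and 3 of 8 arrays correlated best with the other group's array of their own number, a hint from the data and not the design. Pairs share both title codes, but the labels do not say what the codes mark, so a shared culture or batch is not shown. With the replicate block, 7336 genes, 54811 probe sets, 5413 exon-usage genes, 56 interaction genes for B code, 0 for last number and 4 lists were called, RELB was at -0.15, and no call of a count, list or RELB changed sides. The interaction by B code moved from 41 to 65 with median centring, 174 with a variance trend and robust fitting, 26 with exon-level means, 128 at an adjusted p under 0.1, and 3 to 33 with 1 array left out. The last-number effect gave 1 gene with exon-level means, its interaction 0 to 3 and the B code effect 0 to 65 with 1 array left out. List calls numbered 10 without the filter, 0 with an estimated correlation, 16 with fry, and 4 to 9 with 1 array left out (8 without uninduced replicate 3, 9 without induced replicate 3). Without the filter, the adjusted p was 0.0473 for the B-cell, hypoxia, integrated stress, unfolded protein, oxidative phosphorylation and mitochondrial ribosome lists, which gained the call, and the p53 (0.978), T-cell (0.817) and fibroblast (0.971) lists reversed. B-cell and integrated stress lists gained the call with the median filter (0.0371) and with quantile normalisation (0.0445), where the fibroblast list reversed (0.992); the B-cell list also gained it without covariates (0.0492). With an estimated correlation the NF-kB target and Hodgkin lists (0.956) and the interferon and AP-1 lists (0.546) lost the call. Fry gave 0.00253 for NF-kB regulators, 0.0222 for alternative targets, 0.000139 for B-cell, 0.0249 for integrated stress, 0.00705 for unfolded protein, 0.027 for oxidative phosphorylation, 0.0286 for mitochondrial ribosome, 0.0201 for antigen presentation, 0.000353 for JAK-STAT, 0.0189 for T-cell, 0.014 for fibroblast and 0.000415 for heat shock genes, and reversed cholesterol genes (0.412). With 1 array left out the adjusted p ran from 0.0374 to 0.116 (B-cell), 0.501 to 0.991 (DNA replication), 0.706 to 0.995 (T-cell), 0.570 to 0.998 (cholesterol), 0.839 to 0.998 (fibroblast), 0.00167 to 0.196 (hypoxia), 0.00768 to 0.149 (integrated stress), 0.0321 to 0.163 (mitochondrial ribosome), 0.0369 to 0.188 (oxidative phosphorylation), 0.627 to 0.998 (p53) and 0.0387 to 0.137 (unfolded protein). RELA and ITGAM lost their calls without single arrays; fewer samples were fitted there, and the cause of the other changes was not tested. The myeloid list gave no value under the median filter, which left too few members. Signal over background limits dim genes, whose differences are understated.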

Other observations

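The comparison of windows between the induction label, B code and last number was chosen after the results were seen. Neighbouring genes moved together in several stretches of the genome, by gene order in GRCh38.p14. The stretch of 25 tested genes from WASHC1 to LURAP1L, which holds JAK2, CD274 and PDCD1LG2, had a median log2 difference of -0.91 between arrays labelled induced and uninduced, with 21 genes lower and 4 higher. The stretch from FAM110C to CYS1, which holds ID2, a regulator of lymphoid differentiation, and SOX11, had a median of -0.95, also with 21 lower and 4 higher. In the other direction, the stretch from FAM161B to JDP2, which holds FOS, had a median of 0.97 with 23 genes higher and 2 lower, that from SERPINF2 to ITGAE 0.89 with 22 higher and 3 lower, and that from NFYB to SELPLG 0.79 with 19 higher and 6 lower. These 5 of 541 windows lay beyond every window of the shuffled gene orders, whose medians ran from -0.85 to 0.66.

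Over all 541 windows, the standard deviation of the medians was 0.239 for the induction label, against a mean of 0.0935 with shuffled order. It was 0.0486 for B code (0.0379 with shuffled order) and 0.0508 for last number (0.0327 with shuffled order), so the spread beyond shuffled order was 0.220 for the induction label and 0.0390 for last number. The window medians of the induction label correlated across windows at 0.112 with those of the last number and at 0.0907 with those of the B code; windows are not independent replicates. A difference in copy number between the cells of the groups may give such stretches, as a hypothesis. The ratio of 2.56 to shuffled order does not decide it. Last number also passed the bar of 1.5 set beforehand (1.56), though its spread beyond shuffled order was far smaller (0.0390 against 0.220). No DNA was measured in the data used here, and genes regulated together in a neighbourhood would give the same.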
